A study of Mus musculus with 6 samples.

How the data were processed

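ATAC-seq libraries were made from the dentate gyrus of individual C57BL/6 mice after infection with AAV carrying EYFP or cFos, per the labels' protocols. The strain label carries a different final number for every sample after the first, so strain was not used to group samples. Groups and replicate numbers were taken from the sample titles, giving 3 EYFP and 3 cFos libraries, each from its own animal. No label gave a date or sequencing batch, so a batch effect could be neither tested nor removed.

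Reads were aligned with Bowtie2 to mm9, per the submitters' processing notes. Each deposited file was a headerless peak list for 1 library, with 5 columns: chromosome, start, end, a peak name beginning with MACS, and a score. The score is the authors' own value for each peak, as deposited, and was not normalized between libraries here. It ran from 50 to 3100 in every list, and 4 or 5 peaks per list sat at 3100. What the score measures, the caller's version and threshold, a control, and the handling of duplicates, mitochondrial reads and the Tn5 offset are not given in the sources used here. No peak scored under 50 in any list, and the score was used to rank or filter peaks within a list; its median was also compared between libraries. The number of called peaks depends on read depth, and their width on depth and fragment length, so both can differ between libraries without a difference in the cells. Read counts were not used here, so no count model could be fitted and no interval for counting error could be given. The number of animals, 3 per group, sets the precision.

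The coordinates were those of mm9, printed 1-based. No mm9 genome or annotation was used here. The gene table at hand was on GRCm38.p6, and 163 chromosome 1 peaks started beyond its last chromosome 1 gene, so its coordinates were not used. Gene names, promoters, exons, gene lists and the AP-1 motif, which had been planned, were not analysed here, and the same holds for the planned check of Fos as the targeted gene. Regions are named by position only.

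The main analysis used chromosomes 1 to 19 and X; chromosome Y peaks, 30 to 54 per library, are treated separately. Peaks of the 6 libraries were merged where they touched or overlapped, and a library counted as calling a region when a peak of it overlapped by at least 1 bp. The merging gave the same 70575 regions as bedtools 2.31.1. Equal-length lists kept the 23986 highest-scoring peaks of each library. Score percentiles are ranks within a library's own list, and a region takes the highest peak of the library in it. Similarity was the Jaccard index in bases. Group means were compared with two-sided exact permutation tests over all 20 assignments of 3 and 3 libraries, for which the smallest p is 0.1. Counts of group-only regions were set beside the same counts for all 20 ordered choices of 3 libraries, for which the smallest one-sided share is 0.05. On simulated lists with the real width distributions, 200 of 200 planted cFos-only and 300 of 300 planted EYFP-only regions were recovered among 34500 regions, with 0 in mixed choices; that tests the counting, not the authors' peak calling. Unlike in the real lists, simulated sites could not touch each other and no library missed a shared site, so this recovery was fixed by the setup.

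Before the data were examined, a rule fixed the regions to name. It took the 10 group-only regions per direction with the highest mean score percentile, the first 5 on equal-length lists, the first 5 that all 6 libraries share, and the chromosome with the largest difference in share of peaks each way. The second region beside the strongest cFos-only one, its neighbours, and chromosome X were named after their values were seen. The alternatives set beforehand were a stricter score (above 93.41, the median of the lists pooled), every sequence name, half-length lists of 11993 peaks, coverage of at least 50% of a region, merging across gaps of 200 bp, leaving out each library, and the replicate number as a block. Setting every peak to 400 bp around its midpoint, and the comparison of median scores with its alternatives, were added after seeing the data. Same-numbered libraries did not deviate together: the correlation of their deviations from the group means, over presence in the merged regions, was -0.0148, -0.00774 and 0.00300 for numbers 1 to 3, so the numbers were not treated as pairs. No 2 libraries were duplicates, the highest Jaccard index being 0.473. Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.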

Results

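Chromatin accessibility was profiled by ATAC-seq, in which the transposase Tn5 inserts sequencing adapters into open DNA, in the dentate gyrus of adult mice. The dentate gyrus is the hippocampal region whose principal neurons are the granule cells. Adeno-associated virus (AAV) had delivered either EYFP, a fluorescent protein that serves as the control, or cFos, a transcription factor of the AP-1 family that neurons make within minutes to hours of being activated. Each library came from a separate animal, with 3 animals per group, all 8 weeks old. The comparison asks which accessible sites accompany forced cFos expression, within a series on how neuronal activity changes accessibility in the adult brain. The deposited data were one list of called peaks per library. The EYFP lists held 29932, 44321 and 33056 peaks in replicates 1 to 3, and the cFos lists held 26764, 24040 and 34743. Read depth was unknown, because peak lists carry no read counts, so a site missing from a list was not called there and was not shown to be closed.

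The highest-scoring called peaks were common to both groups. Of the 1000 highest-scoring peaks of each library, between 99.8% and 100% lay in regions that all 6 libraries called. The 6 lists merged into 70575 separate regions on chromosomes 1 to 19 and X, and all 6 libraries called 11837 of them. These common regions were wide, with a median of 1128 bp, and made up between 26.9% of the regions of EYFP replicate 2 and 50.2% of those of cFos replicate 2. At the other end, 30815 regions appeared in a single library and had a median width of 366 bp. EYFP replicate 2, the longest list, supplied 9825 of those single-library regions. The 5 common regions with the highest scores lay on chromosome 1 from 24618140 to 24623276, on chromosome 2 from 22442618 to 22446139 and from 98506183 to 98507757, on chromosome 9 from 35112608 to 35113364, and on chromosome 12 from 98299330 to 98300264 (mm9). All but the chromosome 9 region reached the highest score in the lists, 3100, in all 6 libraries. That region scored 3082.11 in cFos replicate 3 and 2910.9 in EYFP replicate 3, and 3100 in the other libraries. No filter for sites that draw wrongly aligned reads was applied here, so whether these 5 regions are open chromatin was not tested.

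On average, libraries of one group shared more accessible sequence with each other than with libraries of the other group. The Jaccard index, the shared bases over the combined bases of a pair of lists, was 0.468 ± 0.00726 (SD, 3 pairs) among EYFP libraries and 0.430 ± 0.00919 (SD, 3 pairs) among cFos libraries. Between groups it was 0.395 ± 0.0349 (SD, 9 pairs) and ranged from 0.325 to 0.432, which overlaps the cFos pairs (0.423 to 0.440) and lies below the EYFP pairs (0.459 to 0.473). cFos replicate 3 shared more with EYFP replicate 1 (0.432) than with cFos replicate 2 (0.427). The pairs share libraries and are not independent. Within-group pairs exceeded between-group pairs by 0.0536 on average. None of the other 9 ways of splitting the libraries into 3 and 3 gave more than 0.0119, and the one-sided exact share of splits was 0.1, the smallest that this design can reach. With every peak set to 400 bp around its midpoint the difference was 0.0304. Without EYFP replicate 2 it was 0.0293, against 0.0262 in the highest other split.

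The cFos lists covered less of the genome, and their peaks were narrower and had lower median scores. The median peak width was 459 ± 21.1 bp (SD, n = 3) in cFos libraries and 561 ± 8.02 bp (SD, n = 3) in EYFP libraries. Every cFos library, from 437 to 479 bp, lay below every EYFP library, from 553 to 569 bp (two-sided exact permutation p = 0.1, the smallest possible with 3 against 3). Peaks covered 15.8 ± 2.66 Mb in cFos and 24.3 ± 5.64 Mb in EYFP libraries (SD, n = 3 each; two-sided exact permutation p = 0.1). The number of peaks on chromosomes 1 to 19 and X was 28464 ± 5562 in cFos and 35736 ± 7568 in EYFP libraries (SD, n = 3 each; two-sided exact permutation p = 0.3), a difference within the spread between replicates. The median score of a list was 88.9 ± 3.11 in cFos and 96.4 ± 6.21 in EYFP libraries (SD, n = 3 each; two-sided exact permutation p = 0.1), from 87.03 to 92.45 against 92.66 to 103.6, on a score that was not normalized between libraries here. Without EYFP replicate 2 the difference in peak number shrank from -7272 to -2997, that in covered sequence from -8.54 to -5.32 Mb and that in median score from -7.58 to -4.00.

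**Figure D1:**
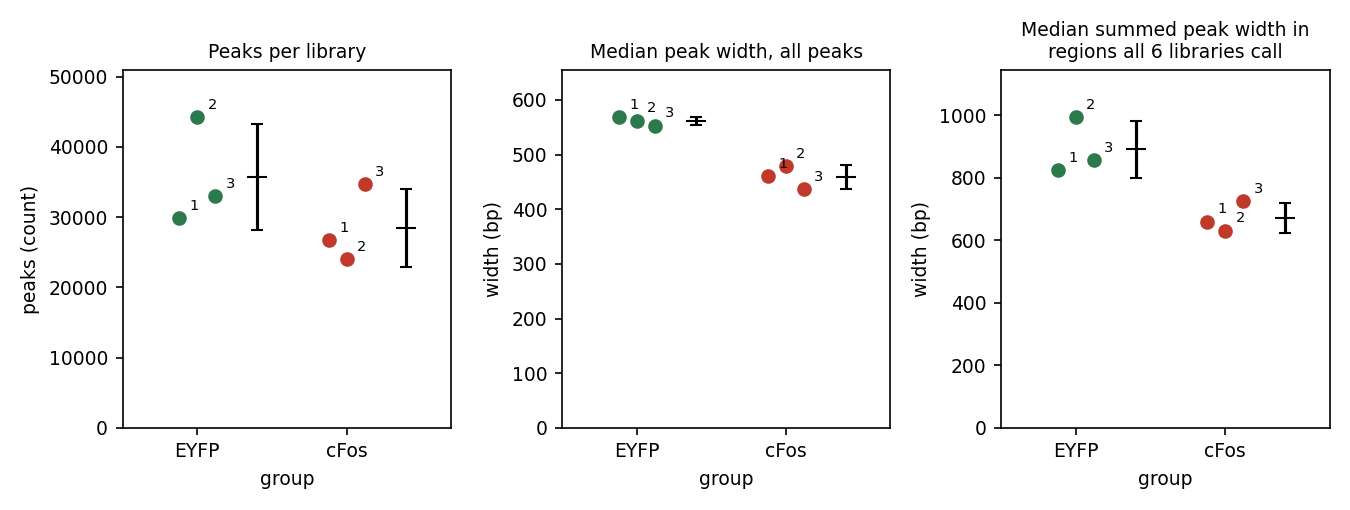
Peaks per library (left, count), median width of all peaks (middle, bp) and median summed peak width in the 11837 regions that all 6 libraries call (right, bp), on chromosomes 1 to 19 and X. Points are libraries with their replicate number, and black bars are the mean and SD of 3 libraries; peak numbers of the groups overlap, whereas all 3 cFos libraries lie below all 3 EYFP libraries in both width panels.

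Accessible regions particular to each group were then taken as those called in 3 of 3 libraries of one group and in 0 of 3 of the other. On the lists as deposited, 317 regions were called in all cFos and no EYFP libraries, and 1390 in all EYFP and no cFos libraries. The EYFP count was the highest of the 20 ordered choices of 3 libraries (one-sided exact share 0.05, the smallest possible), and the highest choice mixing the groups gave 976. The cFos count ranked 8th of the 20 (one-sided exact share 0.4). Regions were not tested one by one, and none is called as changed.

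The asymmetry became smaller when every list was cut to its 23986 highest-scoring peaks, the length of the shortest list. The number of cFos-only regions was then 452 and the number of EYFP-only regions 650. These were the highest 2 of the 20 choices of 3 libraries, and the 18 choices that mixed the groups gave between 111 and 305 regions. The one-sided exact share was 0.1 for cFos and 0.05 for EYFP. Of the 452 cFos-only regions, 227 overlapped one that was also cFos-only on the full lists, and 408 of the 650 EYFP-only regions did so. When a library had to cover at least 50% of a region to count as calling it, the equal-length counts were 403 and 1481, and a mixed choice gave 443. Under that rule a narrower peak can count as no call, and cFos peaks were narrower. Leaving out cFos replicate 3 or any of the EYFP replicates also brought the equal-length cFos count below the highest mixed choice, with 892 against 1010 without cFos replicate 3, and 653 against 839, 648 against 735 and 613 against 832 without EYFP replicates 1, 2 and 3.

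**Figure D2:**
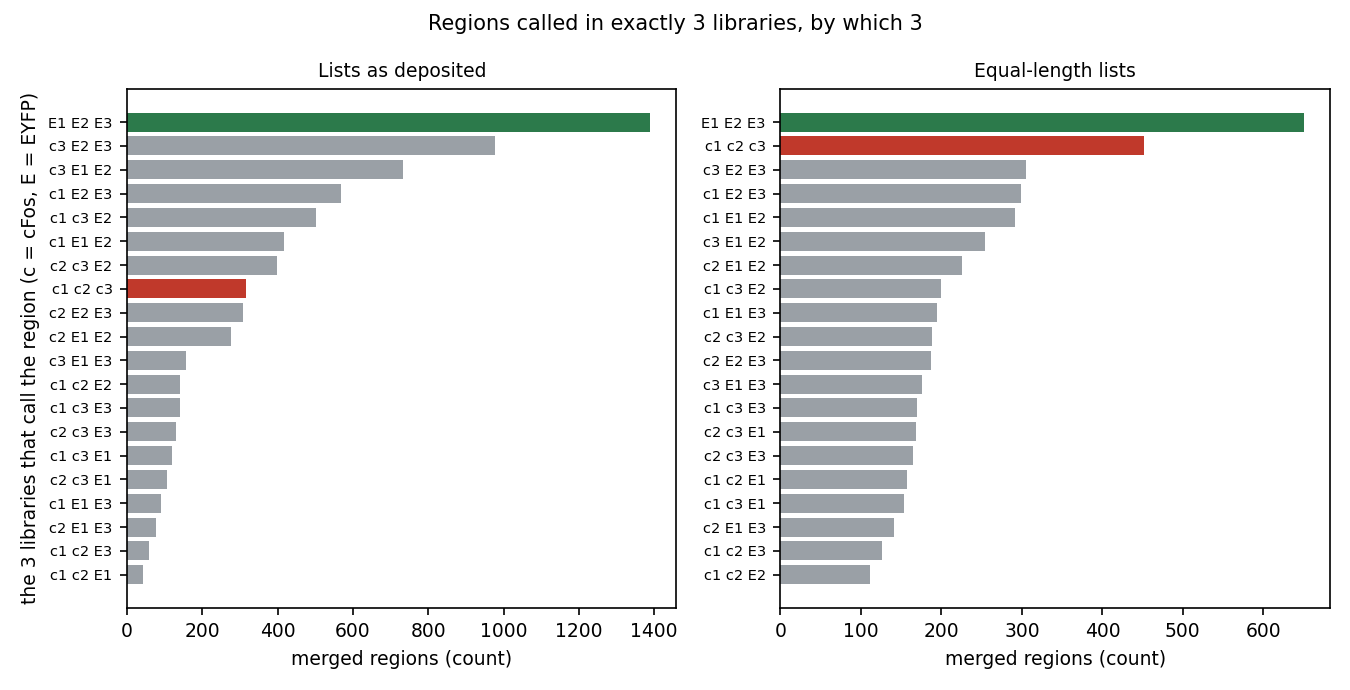
Number of merged regions called in exactly 3 libraries (horizontal axis, count) for each of the 20 choices of 3 libraries (vertical axis), on the lists as deposited (left) and on equal-length lists (right). Red is the choice of all cFos libraries (317 and 452 regions), green that of all EYFP libraries (1390 and 650) and grey the 18 mixed choices.

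The highest-ranked cFos-only region stood apart from the rest of its set. It lay on chromosome 12 from 86816478 to 86817602 (mm9), was 1125 bp wide, and had scores of 148.78, 508.39 and 578.53 in cFos replicates 1 to 3. Those scores placed it at percentiles 73.3, 97.6 and 97.6 of the peaks of their lists. It was the only one of the 317 regions above the 90th percentile in 2 or more libraries, and no EYFP-only region was. A second cFos-only region lay 284 bp away, from 86815594 to 86816193, with scores of 163.65, 96.87 and 163.51. Together both regions spanned 2009 bp. Whether reads from the cFos sequence carried by the virus gave the peaks of these regions could not be told from the data used here. Of the 10 merged regions within 50 kb of the strongest, 4 were called in all 3 EYFP libraries. The nearest of these, from 86814246 to 86815324, scored 141.07, 291.32 and 160.22 in EYFP replicates 1 to 3, scored 139.46 and 146.57 in cFos replicates 1 and 3, and was not called in cFos replicate 2. The next one downstream, from 86826619 to 86827471, was called in all 6 libraries with scores between 167.01 and 247.75.

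**Figure D3:**
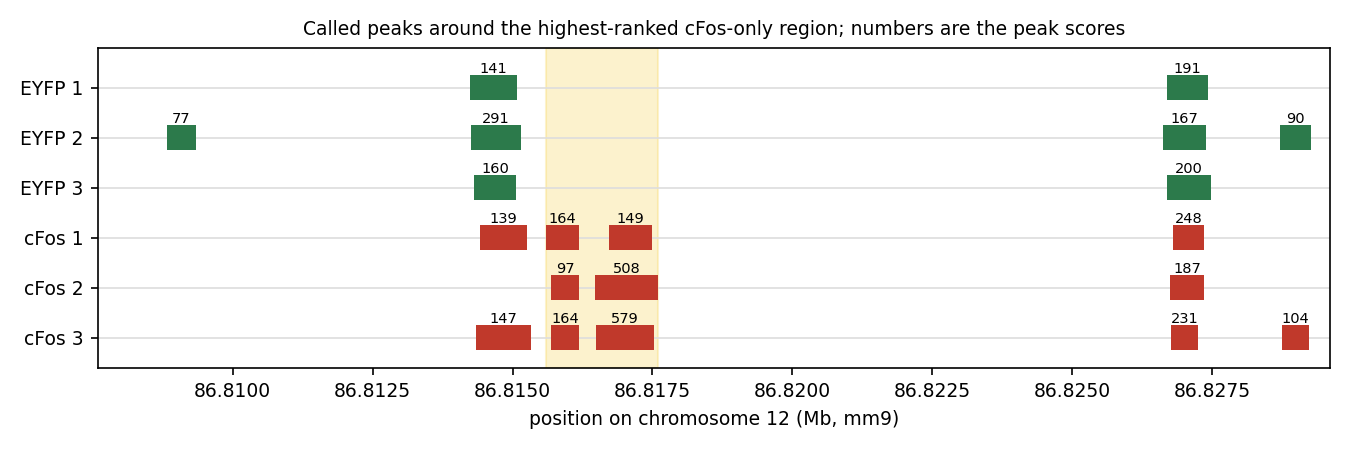
Called peaks of the 6 libraries (rows) along chromosome 12 (horizontal axis, position in Mb, mm9), with the authors' score above each peak; red is cFos and green EYFP. The yellow band, from 86815594 to 86817602, holds 2 peaks in each cFos library and none in any EYFP library, while the nearest region called on either side has peaks of both groups.

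The other cFos-only regions were spread over the genome. Next by mean score percentile were chromosome 13 from 75558005 to 75558640 (81.8 ± 9.40, SD, n = 3), chromosome 3 from 92289504 to 92290301 (81.5 ± 9.45) and chromosome 6 from 47689036 to 47691359 (80.9 ± 3.44). The chromosome 6 region was the widest of the 10 named, at 2324 bp. Chromosome 1 held a region from 70668163 to 70668896 (80.8 ± 7.17) and another from 145383780 to 145384491 (79.3 ± 9.04). The remaining 4 were chromosome 3 from 159323609 to 159324233 (77.5 ± 6.47), chromosome 6 from 17928244 to 17929154 (76.8 ± 8.73), chromosome 10 from 17513692 to 17514314 (75.6 ± 11.4) and chromosome 19 from 45724380 to 45724831 (74.6 ± 0.756). On equal-length lists the first 5 were the regions on chromosomes 12, 13, 3 and 1 already given, and one on chromosome 13 from 17930802 to 17931818, which ranked second (79.8 ± 8.78). That region had weak peaks in the full EYFP lists, with scores of 52.65 in replicate 1 and 94.34 in replicate 2.

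On the full lists the EYFP-only regions were wider and more numerous. Their median merged width was 634.5 bp, against 545 bp for cFos-only regions, and they summed to 957 kb against 184 kb. Peaks of EYFP libraries were wider over the whole lists too (561 against 459 bp), and the numbers came close on lists of the 11993 highest-scoring peaks (234 EYFP-only and 222 cFos-only) and on equal-length lists of peaks above the stricter score (219 and 204). The highest-ranked lay on chromosome 2 from 49685598 to 49686331, at a mean score percentile of 77.3 ± 11.9 (SD, n = 3). It was followed by chromosome 4 from 25817261 to 25818197 (75.6 ± 6.07), chromosome 2 from 51492180 to 51493361 (75.2 ± 11.97) and chromosome 13 from 82957111 to 82957987 (74.5 ± 4.17). Chromosome 5 held a region from 90607045 to 90607788 (74.1 ± 16.3) and another from 136674404 to 136675284 (72.9 ± 7.96). The others of the 10 were chromosome 15 from 14618527 to 14619375 (73.7 ± 8.11), chromosome X from 95440224 to 95440908 (73.7 ± 9.51), chromosome 12 from 59915079 to 59916272 (73.3 ± 7.23) and chromosome 3 from 56688790 to 56689561 (73.2 ± 6.15). On equal-length lists 3 of the first 5 were among these. The other pair, on chromosome 1 from 116488597 to 116489402 and on chromosome 5 from 65664971 to 65665701, had weak peaks in the full list of cFos replicate 3, with scores of 62.65 and 55.45.

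Shares of peaks per chromosome were compared by the exact permutation test only, in which no chromosome can pass adjustment, as its smallest p is 0.1. The groups did not overlap on 4 of the 20 chromosomes, with the cFos share higher on chromosomes 6 and 16 and lower on chromosomes 12 and 15, where chance gives 10%, or 2 of 20. The largest difference toward cFos was on chromosome 3, which held 7.32 ± 0.447% of cFos peaks and 7.05 ± 0.189% of EYFP peaks (SD, n = 3 each; two-sided exact permutation p = 0.5, Benjamini-Hochberg adjusted over 20 chromosomes 0.889). The largest toward EYFP was on chromosome 12, with 4.41 ± 0.183% of cFos and 4.72 ± 0.0758% of EYFP peaks (two-sided exact permutation p = 0.1, adjusted 0.5). Chromosome 3 also held 41 of the 317 cFos-only regions, or 12.9%, and 114 of the 1390 EYFP-only regions, or 8.20%. Chromosome X held 4 cFos-only and 50 EYFP-only regions, or 1.26% and 3.60%. Neither passed after adjustment over the 20 chromosomes, with Fisher's exact p = 0.0123 for chromosome 3 and 0.0318 for chromosome X, both 0.243 after Benjamini-Hochberg adjustment. These tests treat regions as independent, which they are not.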

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

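All tests of explanations in this part were chosen after the results were seen. Chromosome Y lay outside the comparisons and drew attention because more peaks were called on it in cFos than in EYFP lists. The cFos lists held 52 ± 2.65 peaks on chromosome Y and the EYFP lists 34 ± 3.46 (SD, n = 3 each; two-sided exact permutation p = 0.1, the smallest possible), with every cFos library, from 49 to 54, above every EYFP library, from 30 to 36. Splitting of wide peaks by narrower calling is argued against, because cFos libraries called 18.3 more separate merged Y regions (46 to 54 against 26 to 35). Only 1 of the 79 merged Y regions was called in all cFos and no EYFP libraries, and the covered sequence overlapped between groups (37.1 ± 6.26 against 31.2 ± 2.99 kb). A difference in how multi-mapping reads were kept, an unrecorded batch, and the virus delivered remain open, as no read data or sequence were used here.

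The narrower cFos peaks are the second pattern, with medians of 437 to 479 bp against 553 to 569 bp. Different sites being called is argued against by the 11837 regions common to all libraries, where the peak widths of a library were summed per region. The cFos medians of that sum (630 to 725 bp) stayed below the EYFP medians (823 to 994 bp), a mean difference of -219 bp. Unlike the medians per peak, the sum also depends on how many peaks a library has in a region. A constant length added to each peak by the caller is argued against as the whole cause, since the difference grew from -58.3 bp at the 10th percentile of width to -200 bp at the 90th, a change of -142 bp. Lower read depth in the cFos libraries stays open. Median scores of whole lists were lower in every cFos library, but in the common regions the cFos medians (147 to 221) overlapped the EYFP medians (190 to 302), a mean difference of -57.9 (two-sided exact permutation p = 0.3), with cFos replicate 3 above EYFP replicates 1 and 3. The distribution of fragment lengths, an unrecorded batch and the cFos treatment itself stay open too and could not be tested from peak lists.

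The cFos-only regions on chromosome 12 between 86815594 and 86817602 are the third pattern. A general opening of that neighbourhood stays open, because the 3 other regions within 50 kb that all 6 libraries called went both ways. Their mean score percentile, cFos minus EYFP, differed by -4.60, -2.29 and 7.65, with a median of -2.29. In the last, from 86826619 to 86827471, the percentiles were apart (81.3 to 87.1 in cFos and 69.8 to 79.5 in EYFP libraries) but the scores overlapped (187.15 to 247.75 and 167.01 to 199.78), and percentiles also depend on the length of a list. A candidate explanation is that reads from the cFos sequence carried by the virus aligned to the mouse Fos gene. The GRCm38.p6 gene table puts Fos on chromosome 12. That chromosome holds 4.69% of all merged regions and 7.26% of the cFos-only regions. These shares concern the chromosome only. Positions along it were not compared with that of Fos, so the shares cannot decide whether the match is a coincidence. The chromosome alone does not place the regions in the exons of Fos. No mm9 annotation was used, so where the regions lie relative to Fos was not examined here. Viral sequence was therefore not told apart from a response of the locus itself.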

How the results depend on the processing

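The differences in peak number, covered sequence, median width and median score kept their direction under the 9 alternatives run for them (stricter score, every sequence name, each library left out, and the replicate block), from -10385 to -2997 peaks, from -10.6 to -5.32 Mb, from -113 to -91.3 bp and from -9.47 to -4.00 in score, as did the similarity excess under 11 (those, half-length lists and fixed width), from 0.0293 to 0.0738; with 3 libraries per group none of the exact tests could fall under 0.05. EYFP-only counts exceeded every mixed choice of libraries under all 13 alternatives on equal-length lists and the 12 on full lists. The cFos-only count did so under 8 of 13 on equal-length lists and under 0 of 12 on full lists, where the half-length lists are not counted again because they are the same on both kinds. These tallies are not independent checks. They include the replicate block, which repeats the main counts, and settings close to the main one, such as every sequence name. A stricter score gave 90 cFos-only and 758 EYFP-only regions on full lists and 204 and 219 on equal-length lists, from fewer peaks. Half-length lists gave 222 cFos-only and 234 EYFP-only regions. Requiring 50% coverage of a region gave 2552 EYFP-only regions on full lists and 1481 on equal-length lists. These can include regions where a narrower cFos peak covered less than 50%, so peak width was not separated from absence of a call. Leaving out each library in turn, which eases the criterion by construction, gave 400 to 1213 cFos-only and 1852 to 3604 EYFP-only regions on full lists, and 613 to 1415 and 1098 to 1387 on equal-length lists. With the replicate number as a block, the counts were 317 and 1390 on full lists and 452 and 650 on equal-length lists, identical by construction, and the exact sign-flip p for median width was 0.25, the smallest that 3 pairs allow. It changed no call. Chromosome Y, wider merging and fixed-width peaks moved no count by more than 1.5 times. Every statement here is limited by unknown read depth, since a site that is not called may be open below the threshold.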

Other observations

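The tests in this part were chosen after the values were seen. With all 6 libraries, regions called only in cFos libraries had the highest median score percentile of the 20 sets confined to 3 libraries, but their lead over EYFP-only regions depended on cFos replicate 3. Their median score percentile was 43.9, that of EYFP-only regions 38.4, and that of the 18 mixed choices of 3 libraries between 28.4 and 36.9. Only 1 of the 20 ordered choices, the cFos one, reached 43.9, and the highest of the others was 38.4. On equal-length lists the values were 40.2 for cFos-only, 33.7 for EYFP-only and at most 32.2 for mixed choices. Percentiles were ranked anew in the cut lists, so a peak falls further in a list that lost more peaks. EYFP replicate 2 was cut from 44285 to 23986 peaks and cFos replicate 2 was not cut, so list length enters the equal-length values. With 400 bp peaks on full lists the values were 44.2, 38.4 and at most 37.0. Leaving out each library in turn kept the cFos value above the highest mixed choice in each of the 6 cases, the closest being 34.6 against 33.2 without cFos replicate 3. The order against EYFP-only regions reversed without cFos replicate 1 (40.3 against 40.8), 2 (35.4 against 40.03) or 3 (34.6 against 41.6), but the cFos set then needs 2 libraries and the EYFP set 3, and EYFP-only regions fell likewise, to between 32.5 and 34.3, without an EYFP library. With 1 library of each group left out, so that both sets need 2, cFos-only regions were higher in 5 of 9 cases, by up to 4.99, and lower in 4. They were lower in each of the 3 cases without cFos replicate 3, by -2.27, -0.422 and -2.30, and in the case without cFos replicate 2 and EYFP replicate 3, by -0.344. They stayed above the highest mixed choice in 8 of the 9, the exception being 35.27 against 35.33 without cFos replicate 3 and EYFP replicate 3. With 20 choices the share cannot fall under 0.05.

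On the full lists 46 of the 317 cFos-only regions, or 14.5%, lay above the median score of their list in all 3 cFos libraries, against 110 of the 1390 EYFP-only regions, or 7.91%. On equal-length lists the numbers were 50 of 452, or 11.1%, and 16 of 650, or 2.46%. These shares come from the same score percentiles as the medians above, whose cFos lead over EYFP-only regions depended on cFos replicate 3. No mixed choice and no left-out library is set beside them. The median to be exceeded also differed between the groups, from 87.03 to 92.45 in full cFos lists and from 92.66 to 103.6 in full EYFP lists. Cutting to equal length removed the most peaks from EYFP replicate 2 and none from cFos replicate 2. The shares therefore do not compare the groups at the same score.

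The strict sets leave out regions called unevenly between the groups in other ways. On equal-length lists 550 regions were called in 3 cFos and 1 EYFP libraries, and 1375 in 1 cFos and 3 EYFP libraries. A further 1959 were called in 2 cFos and no EYFP libraries, against 2020 in 2 EYFP and no cFos libraries. Called in 3 cFos and 2 EYFP libraries were 1080 regions, and in 2 cFos and 3 EYFP libraries 2484. For comparison, 1652 regions were called in 2 libraries of each group. These classes hold different numbers of library combinations, and whether their counts follow the groups was not tested.

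The splits of the 6 libraries into 3 and 3 number 10, too few for a share under 0.05. The real split was the top 1 of 10 on both kinds of list. It gave 1707 regions found in all of one side and none of the other on full lists, against 1019 in the highest other split, and 1102 against 468 on equal-length lists.

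Across the 11837 regions common to all libraries, peak scores of EYFP libraries correlated with each other at Spearman's rho from 0.809 to 0.852. Those of cFos libraries correlated at 0.745 to 0.808, and pairs between groups at 0.739 to 0.813, a range that overlaps those of the cFos and of the EYFP pairs. These correlations are across regions, which are not independent replicates.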
